A study of Mus musculus with 16 samples.

How the data were processed

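The series holds 16 RNA-seq libraries of mouse embryonic stem cells that carry an inducible Cdx2 transgene. The cells express the transgene once doxycycline is withdrawn. Poly(A) RNA libraries were made with a stranded kit, per the labels' protocols. Per the submitters' processing notes, STAR 2.5.2b, Cufflinks 2.2.1, Cuffdiff and the mouse build mm9 were used, with no role or order given. Whether the counting used the strand is not given in the sources used here.

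The authors deposited 2 gene tables of pairwise comparisons with 24319 genes each, in the layout of Cuffdiff. Their values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) per condition, per the file headers. The tables were normalised separately, so tests were made within a table. The ALKBH1 table holds 10 conditions and 45 pairs, with 1 library per condition. The SATB1 table holds 4 conditions and 6 pairs for 6 libraries. In that table the 2 knockout clones share 1 value per day, and how they were combined is not given in the sources used here. The deposited p-values, q-values and log2 fold changes are those of the authors, per the file headers, and calls taken from them are named as the authors'. In each table, 1 arm carries a column name of its own and was matched to its samples by elimination, since the other names match the titles. The title of the day 6 ALKBH1 control library names the control, while its genotype label names overexpression. The title was used. Of 2105 genes called between the arms without day 6, in the fit described below, 95.5% kept their direction at day 6. That argues for the title over the genotype label.

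A gene has a value in several pairs of a table. Of 243190 such values in the ALKBH1 table, 15 differed between pairs, and of 97276 in the SATB1 table, 2 did, and the most frequent one was used. Values were taken as log2(FPKM + 1), so a difference understates the change of low genes. Genes with a mean FPKM of at least 1 over a table's conditions were kept, which left 12704 genes in the ALKBH1 table, 12023 in the SATB1 table and 11635 in both. FPKM hold no counts. The relative depth of libraries was read from the steps between the low values (below 0.5 FPKM), where 1 fragment sets the smallest value of a gene. A listed 0 can be a failed estimate, since genes that every cell uses were also at 0.

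In the ALKBH1 table limma 3.58.1 (R 4.3.3) was fitted to 3 contrasts. The arm effect (overexpression minus control) had day as a block of 5 levels and 4 residual degrees of freedom. The time course had arm as a factor and a common slope per day, with 7 residual degrees of freedom. The slope difference was the arm-by-day term, with 6. Adjusted p is by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. No arm has 2 libraries of the same day, so the spread measured is that of the difference between days, and culture or clone differences between the arms are part of the arm effect. In the SATB1 table limma was fitted to genotype with day as a block over the 4 condition values, with 1 residual degree of freedom. Other SATB1 comparisons and those of 1 value with 1 value were not tested and are given as the number of genes that differ by at least 1 (a fold of 2). Correlations are across genes, which are not independent replicates, with a standard deviation from 200 bootstraps over chromosomes.

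The analysis used 19 gene lists with 347 entries (345 genes). They are pluripotency, formative and primed pluripotency, trophoblast stem and trophectoderm, differentiated trophoblast, primitive endoderm, primitive streak and mesoderm, neuroectoderm, feeder fibroblast, cleavage-stage-like, germline genes silenced by promoter DNA methylation, DNA and RNA methylation enzymes, p53 targets, proliferation, FGF and ERK response, Hox genes, epithelial junction, hypoxia and glycolysis, cholesterol synthesis, and imprinted genes. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from the limma fit to the SATB1 table and the 5 alternatives that the closing section names as chosen later. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation. For comparisons without a test, the median of a list was placed among 10000 random lists of the same size, matched on mean expression in 50 bins.

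Named genes are Alkbh1, Satb1 and Cdx2, and for each limma contrast the 10 largest coefficients per direction past the threshold, for the arm effect with 1 sign at every day. For the SATB1 knockout they are the 10 per direction by the smaller difference of both days and the 5 per direction at each day, with at least 5 FPKM in a value compared, and up to 4 members of each list. Unnamed and predicted genes and small RNAs with symbols in Mir or Snor were left out of the names and not of the counts. Other genes are said to be chosen after their values were seen.

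The limma fits were tested on simulated data for 12704 genes, with 50 changed genes per size. For the arm effect, 14% of the genes changed 1.5-fold, 80% at 2-fold, 94% at 4-fold and 100% at 8-fold were recovered, with 4 false calls. For the time course, slopes of 0.1, 0.2, 0.4 and 0.8 per day were recovered in 2, 50, 86 and 96% of genes, and for the slope difference in 0, 0, 36 and 88%. For SATB1 genotype, over 12023 genes, 14, 48, 50 and 50 of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered, with 22 false calls. The simulated noise was independent between genes. In the real SATB1 fit Rps27, with a coefficient of 4.24, was not called, so these rates need not hold there.

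Alternatives were the pseudocount (0.1 and 5), the filter (none and a mean of at least 5 FPKM), quantile and median scaling, limma with a trend in the variance prior, each day left out in turn, no day block, single arms, and a fold of 1.5 in place of 2 for the counts by size. GC content and transcript length were removed in 20 bins each as a check, with values for 99.7% of the ALKBH1 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are those of the authors' files, build mm9. Exons and sequences of that build were not used here.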

Results

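RNA-seq was carried out on mouse embryonic stem cells (ES cells) in which withdrawal of doxycycline switches on Cdx2, a transcription factor that directs cells to the trophoblast lineage. One set of libraries followed a control arm and an arm overexpressing ALKBH1, an enzyme reported to remove N6-methyladenine from DNA, at days 0, 2, 4, 5 and 6 after withdrawal, with 1 library per arm and day (10 libraries). The other set compared SATB1 knockout cells with SATB1+/- control cells at days 0 and 4. SATB1 is a chromatin organiser. This set had 6 libraries, of which 2 per day were knockout clones that share 1 value in the table. The title of the series names DNA N6-methyladenine as an antagonist of SATB1 in early development, and the comparisons address what each perturbation did to gene expression before and during the Cdx2-driven change. No group had replicates of the same day with values of their own, so all values are single.

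The sum of FPKM ranged from 442816 to 937726 in the ALKBH1 libraries and from 404925 to 426382 in the SATB1 conditions. Total read counts are not given by FPKM. From the steps of low values, the ALKBH1 control libraries of days 0, 2, 4, 5 and 6 had a depth of 0.807, 0.392, 1, 0.779 and 0.314 relative to control day 4. The overexpression libraries had 0.847, 0.0934, 0.611, 0.454 and 1.12, where the step of day 2 was weak. In the SATB1 table control day 4 had 1.44 times the depth of control day 0, and the knockout values showed no clear step. A small RNA, Mir6236, had 345806 FPKM in control day 0 and 290406 in overexpression day 4. There the 10 highest genes made up 47.9% and 42.6% of the FPKM sum, against 7.16 to 27.6% in the other ALKBH1 libraries. Gapdh had 4.6 to 99.4 FPKM in the ALKBH1 table and 1731 to 2031 FPKM in the SATB1 table, which were normalised separately. Of 172 genes above 300 FPKM in the SATB1 table, 13 never passed 5 FPKM in the ALKBH1 table, most of them ribosomal protein genes.

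Alkbh1 (chromosome 12, 88769028 to 88813249) had 31.6, 35.4, 21.9, 21.1 and 20.2 FPKM in the control at days 0, 2, 4, 5 and 6. In the libraries labelled overexpression it had 80.2, 47.9, 29.97, 23.2 and 18.7 FPKM. The difference on the log2(FPKM + 1) scale was 1.31 at day 0, 0.43 at day 2, 0.44 at day 4, 0.13 at day 5 and -0.10 at day 6, so the day 6 library labelled overexpression was not above its control. The arm coefficient was 0.44 ± 0.21 (SE, 5 days) and did not pass the threshold (limma, adjusted p = 0.155). Satb1 (chromosome 17, 51875512 to 51972615) increased over time, from 2.68 to 32.9 FPKM in the control and from 3.17 to 32.6 FPKM in the overexpression arm (slope 0.57 per day, limma adjusted p = 0.00101). In the SATB1 table Satb1 had 2.75 FPKM in the control and 2.32 in the knockout at day 0, and 16.1 and 7.50 at day 4. The value is over the whole gene and the deleted part is not given in the labels, so it does not check the genotype. Cdx2 (chromosome 5, 148112476 to 148118825) went from 3.45 FPKM at day 0 to 95.1 at day 4 and 22.0 at day 6 in the control. In the overexpression arm it was 2.68, 56.5 and 16.2, with a maximum of 72.2 at day 2. In the SATB1 table it went from 1.30 to 31.3 FPKM in the control and from 1.84 to 36.2 in the knockout.

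**Figure D1:**
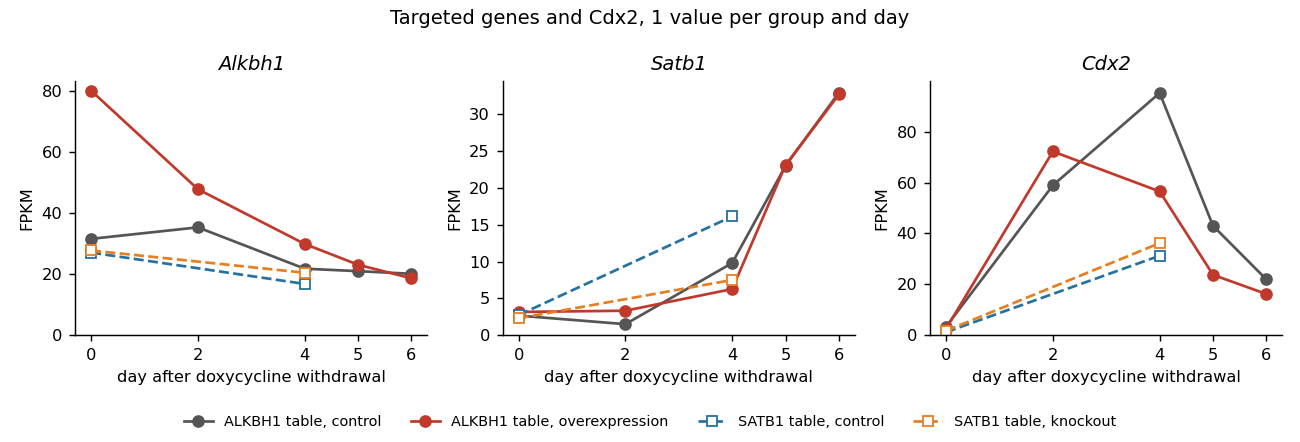
FPKM (y axis) of Alkbh1, Satb1 and Cdx2 by day after doxycycline withdrawal (x axis), with 1 point per library or condition. Filled circles are the ALKBH1 table, open squares the SATB1 table, and lines join the days of a group. Alkbh1 was at 80.2 FPKM in overexpression day 0 against 31.6 in the control, and at 18.7 against 20.2 at day 6.

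The effect of ALKBH1 overexpression across days was examined first, where overexpression is the label of the arm and not a level measured at each day. The genes that rose most included X-linked Rhox and Xlr genes and the noncoding RNAs H19 and Xist. Rhox13, a homeobox gene of the X-linked Rhox cluster (chromosome X, 35474017 to 35483143), had 43.0 to 84.7 FPKM against 0.707 to 2.37 in the control (4.81 ± 0.25, SE, limma adjusted p = 0.00116, higher at 5 of 5 days). Rhox10 (3.4) and Rhox1 (3.23) of the same cluster, Sohlh2, a transcription factor of early germ cells (3.14), the X-linked Xlr4a (3.08) and Xlr3a (3.06), Tuba3a, a tubulin gene (4.23), and Ly6k (3.45) followed. H19, an imprinted noncoding RNA (chromosome 7, 149761435 to 149764051), went from 12.2 to 255 FPKM in the control and from 55.5 to 2565 in the overexpression arm (3.77 ± 0.40, SE, limma adjusted p = 0.00468). Xist, the noncoding RNA that silences an X chromosome (chromosome X, 100626856 to 100680296), stayed between 0.178 and 0.792 FPKM in the control and went from 1.52 to 102 FPKM in the overexpression arm (3.75 ± 0.79, SE, limma adjusted p = 0.0193). Xist shares its locus with the antisense Tsix, and reads of both cannot be told apart if the strand was not used. Rhox and Xlr genes belong to families of similar sequence.

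The genes that fell most included several for contractile and intermediate filament proteins. Tagln (chromosome 9, 45671774 to 45744141) had 115, 210, 71.9, 12.8 and 5.42 FPKM in the control and 11.8, 4.11, 2.09, 1.5 and 0.446 in the overexpression arm (-3.54 ± 0.50, SE, limma adjusted p = 0.00734). The actins Acta2 (-3.07) and Acta1 (-2.54), vimentin (Vim, -2.71), the myosin light chain Myl9 (-2.28), the interferon-induced Ifitm3 (-2.85), the myelin protein gene Pmp22 (-2.49) and Wls, which carries Wnt proteins out of the cell (-2.08), were lower as well. Hmga1-rs1 (-2.43) and Hist1h2af (-2.09) were also among the lowest, but both have near-identical copies and were listed at 0 in some libraries. Of the 10 feeder fibroblast genes tested, 3 fell, namely Tagln, Acta2 and Vim, and the list did not pass (camera adjusted p = 0.105). Its median difference was -1.36, -2.37 and -0.84 at days 0, 2 and 4, at or below percentile 0.01 of random lists, and -0.40 (percentile 2.91) and 0.008 (percentile 39.6) at days 5 and 6. The cells had been grown on feeder cells before day 0. Col1a1, a fibroblast collagen, had a coefficient of -1.02 and did not pass.

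Among the lists, 3 passed at the preset correlation and none with an estimated correlation. Germline genes silenced by promoter DNA methylation rose, with 13 of 15 past the threshold and a median of 1.29 (camera adjusted p = 3.6e-07, 0.466 with an estimated correlation). Dazl (2.04), Sycp1 (1.78), Mael (1.63) and Slc25a31 (1.62), which act in germ cells, had the largest coefficients, and Ddx4 (-0.12) and Tex19.1 (0.33) did not pass. FGF and ERK response genes fell, with 8 of 13 past the threshold and a median of -0.98 (camera adjusted p = 0.0122, 0.466 with an estimated correlation). They included the feedback regulators Dusp4 (-1.29), Dusp6 (-1.24), Spry4 (-1.12) and Spry2 (-1.12). Proliferation genes fell, with 9 of 18 past the threshold and 11 adjusted over the list alone (camera adjusted p = 0.00128, 0.58 with an estimated correlation). The mitotic kinases Aurka (-1.0) and Plk1 (-0.85) and the cell cycle activator Cdc20 (-0.87) were among them. Adjusted over the list alone, 13 germline and 8 FGF and ERK genes passed.

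**Figure D2:**
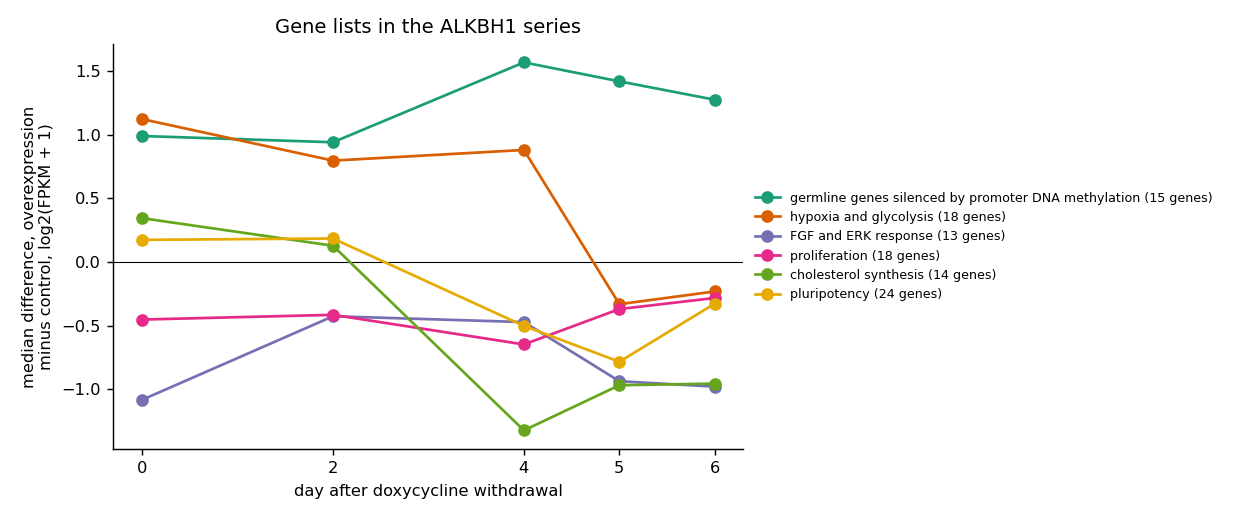
Median difference in log2(FPKM + 1), overexpression minus control (y axis), over the genes of 6 lists at each day after doxycycline withdrawal (x axis), with 1 library per arm and day. The germline list lies between 0.94 and 1.57 at the 5 days, and the cholesterol synthesis list goes from 0.34 at day 0 to -0.96 at day 6.

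The other lists did not pass for the arm effect. In the hypoxia and glycolysis list 7 of 18 genes rose, including Ndrg1 (1.33), Pgk1 (1.31) and Adm (1.29) (camera adjusted p = 0.0659). Its median difference was 1.12, 0.80 and 0.88 at days 0, 2 and 4, but -0.33 and -0.23 at days 5 and 6. Of the 14 cholesterol synthesis genes 4 fell, Ldlr (-1.20), Lss (-1.17), Fdps (-0.97) and Dhcr24 (-0.59) (camera adjusted p = 0.0659). In the trophoblast stem and trophectoderm list 6 of 21 rose, including Plet1 (1.05) and Ets2 (0.97), and 3 fell, Bmp4 (-1.25), Msx2 (-1.16) and Krt8 (-1.08) (adjusted p = 0.81). In pluripotency Dppa5a rose (1.09) and 4 of 24 fell, Lefty1 (-1.99), Nr0b1 (-1.37), Gdf3 (-0.81) and Zic3 (-0.80) (adjusted p = 0.291). The pluripotency median was 0.17 and 0.18 at days 0 and 2, but -0.50, -0.78 and -0.33 at days 4, 5 and 6. Of 17 imprinted genes H19 rose and 5 fell, including Peg3 (-1.69) and Phlda2 (-1.10) (adjusted p = 0.405). Among the methylation enzymes Tet2 rose (0.89) and Mettl3 (-0.60), Alkbh3 (-0.40) and Uhrf1 (-0.36) fell (adjusted p = 0.373). The remaining adjusted p were 0.0659 for cleavage-stage-like (1 of 6 rose), 0.0877 for formative and primed pluripotency (2 of 10 fell), 0.14 for differentiated trophoblast (2 of 15 rose, Pcdh12 and Plac1), 0.14 for epithelial junction (3 of 18 fell), 0.146 for primitive endoderm (2 of 12 rose), 0.226 for Hox genes (0 of 7), 0.261 for primitive streak and mesoderm (2 of 4 rose), 0.579 for neuroectoderm (2 of 5 rose) and 0.895 for p53 targets (2 of 15 rose and 1 fell). For neuroectoderm, p53 targets and trophoblast stem and trophectoderm the median was below 0 and the mean and the test were above 0. Adjusted over the list alone, 8 trophoblast stem and trophectoderm genes and 2 cleavage-stage-like genes rose, 1 differentiated trophoblast gene rose and 3 formative genes fell, and the counts of the other lists in this paragraph were the same.

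In all, 1874 genes were higher and 1723 lower of 12704 in the overexpression arm (limma, adjusted p below the threshold). The difference had 1 sign at all 5 days in 5137 genes (40.4%), where independent days without a difference would give 6.25%. The days of an arm are not independent, so a lasting difference between the cultures also raises this share. Without day 5 the counts were 806 and 568, without day 4 they were 929 and 776, without day 6 they were 1128 and 977, and without day 0 they were 1265 and 1115. With neither day 0 nor day 4, which leaves 3 days and 2 residual degrees of freedom, limma called 0 genes (smallest adjusted p = 0.0886, 3793 at an unadjusted p below 0.05). The coefficients of the 3597 genes had the same sign and a median size of 0.65 against 0.67 over 5 days. These genes were called on days that include the 3 kept, so this is no independent check. Without the day block limma called 297 higher and 269 lower. Genes of whole chromosomes were shifted together in these libraries. Relative to the other chromosomes, the median over genes lay at -0.36 on chromosome 2, -0.35 on chromosome 10 and 0.47 on chromosome X, as means over 5 days. In the SATB1 knockout, compared with its control, chromosome 11 lay at -0.30 and 85.9% of its 795 genes were below 0.

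**Figure D3:**
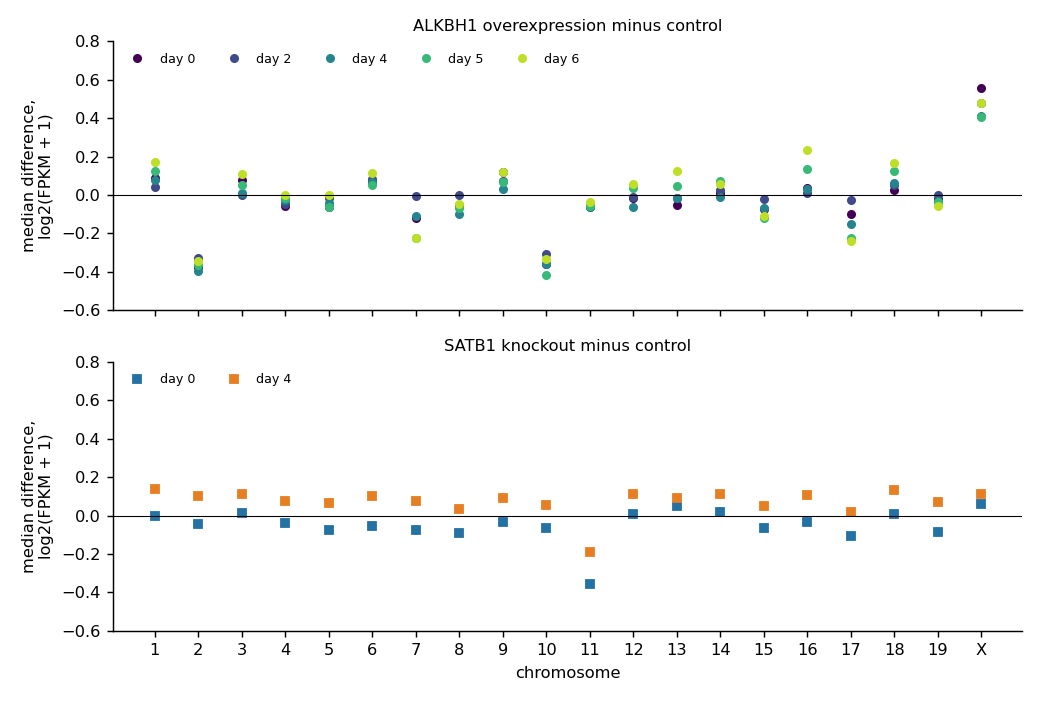
Median difference in log2(FPKM + 1) over the genes of each chromosome (x axis), for ALKBH1 overexpression minus control at 5 days (top) and SATB1 knockout minus control at 2 days (bottom). Each point is 1 chromosome at 1 day. In the top panel chromosome X lies between 0.41 and 0.56 and chromosome 2 between -0.39 and -0.33, and in the bottom panel chromosome 11 lies at -0.36 and -0.19.

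At single days, the genes that differed by at least 1 numbered 908 higher and 759 lower at day 0, 786 and 521 at day 2, 968 and 664 at day 4, 629 and 937 at day 5, and 783 and 922 at day 6. The authors' deposited table marks far fewer genes of the same-day pairs as significant. It lists none at day 0, Col3a1, H19 and Mrc1 at day 2, Mir6236 and Sparcl1 at day 4, Pou4f3 and Xist at day 5, and Clec12a and Nlrp4f at day 6. These differences have no replicate check.

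The time course asked which genes rose or fell after doxycycline withdrawal in both arms. The steepest rise was that of Plac1, a placental gene (chromosome X, 50423179 to 50467582), which went from 2.43 to 374 FPKM in the control and from 3.38 to 1169 FPKM in the overexpression arm (1.41 ± 0.12 per day, SE, limma adjusted p = 0.000141). Elf5, a trophoblast stem cell factor, rose by 1.07 per day, and Dppa1 (1.33), Adh1 (1.30), Ldoc1 (1.16), Cd82 (1.15), Cdh5 (1.09), Entpd1 (1.06), Serpinb9e (1.04) and Tinagl1 (1.03) had similar slopes. Nanog, a core pluripotency factor (chromosome 6, 122657507 to 122664651), went from 154 to 3.06 FPKM and from 404 to 1.80 FPKM (-1.17 ± 0.14 per day, SE, limma adjusted p = 0.000306). Stmn2 (-1.38), Tdgf1 (-1.30), Sox2 (-1.17), Pla2g1b (-1.15), Fgf4 (-1.09), Tdh (-1.07), Lefty1 (-1.06), Jam2 (-1.05) and Platr10 (-1.05) were the others with the steepest falls.

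By list, 8 lists passed at the preset correlation and none with an estimated correlation, where the adjusted p of these 8 lay between 0.316 and 0.418. Of the pluripotency genes 23 of 24 fell (camera adjusted p = 1.9e-11), and 18 of 21 trophoblast stem and trophectoderm genes rose and 1 fell, Bmp4 (adjusted p = 7.2e-09). Cdx2 itself, with its maximum at days 2 to 4, had a slope of 0.33 (limma adjusted p = 0.209). Epithelial junction genes rose, 16 of 18, including Cldn4 (0.52), Cldn3 (0.50), Cldn7 (0.49) and Dsp (0.45) (adjusted p = 3.8e-05). Differentiated trophoblast genes rose, 11 of 15, including Hand1 (1.00) and Syna (0.81) (adjusted p = 9e-05). Lists that fell were proliferation (13 of 18, adjusted p = 0.000131), germline genes (10 of 15, 1 rose, Tex19.1, adjusted p = 0.00112), cleavage-stage-like (4 of 6, adjusted p = 0.0237) and feeder fibroblast (6 of 10, 1 rose, Postn, adjusted p = 0.0283). Adjusted p was 0.0574 for formative and primed pluripotency, 0.069 for FGF and ERK response, 0.0826 for p53 targets, 0.162 for imprinted genes, 0.162 for neuroectoderm, 0.175 for primitive endoderm, 0.19 for methylation enzymes, 0.217 for cholesterol synthesis, 0.396 for Hox genes, 0.396 for hypoxia and glycolysis and 0.976 for primitive streak and mesoderm. Adjusted over the list alone, counts were the same except for differentiated trophoblast (13 rose), cleavage-stage-like (5 fell), imprinted genes (5 fell in place of 4) and hypoxia and glycolysis (0 fell in place of 1). In total 3278 genes rose and 2799 fell, and 1980 and 1827 in the control arm alone, 1010 and 1038 in the overexpression arm alone. With median scaling 2809 rose and 3333 fell. Without day 6, 2209 rose and 1864 fell.

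The arm-by-day term asked which genes changed at another rate in the overexpression arm. No single gene passed (limma, 0 of 12704, smallest adjusted p = 0.168, 1488 at an unadjusted p below 0.05). The cholesterol synthesis list passed at the preset correlation and not with an estimated one, with a median slope difference of -0.27 per day over 14 genes (camera adjusted p = 1.1e-08, 0.904 with an estimated correlation) and 0 of 14 past the threshold singly. The list median of overexpression minus control was 0.34, 0.13, -1.32, -0.97 and -0.96 at days 0, 2, 4, 5 and 6. Hypoxia and glycolysis genes had a median of -0.23 per day over 18 genes (camera adjusted p = 0.000119, 0.904 with an estimated correlation). Adjusted over the list alone 7 cholesterol synthesis genes and 3 hypoxia and glycolysis genes had a lower slope in overexpression, and 0 of either passed over all genes. Of the other lists only neuroectoderm had a gene past the threshold adjusted over the list alone (1 with a higher slope). The adjusted p was 0.138 for feeder fibroblast, germline, imprinted and primitive endoderm genes, 0.257 for p53 targets, 0.352 for pluripotency, 0.39 for cleavage-stage-like, 0.557 for formative and primed pluripotency, 0.57 for differentiated trophoblast, epithelial junction, Hox, neuroectoderm and primitive streak genes, 0.688 for trophoblast stem and trophectoderm, and 0.75 for FGF and ERK response, methylation enzymes and proliferation. The median and the test differed in sign for FGF and ERK response (median -0.04) and for proliferation (median 0.0053, which turned below 0 with quantile scaling).

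SATB1 knockout was compared with SATB1+/- control at day 0 and day 4, with 1 value per genotype and day. A fit of genotype with day as a block, chosen after the data were examined, has 1 residual degree of freedom and called 0 of 12023 genes (limma, smallest adjusted p = 0.188, 1392 at an unadjusted p below 0.05), and the differences of single days were not tested. With a trend in the variance prior it called Cdkn1c, Npcd, Rps27 and Usp26 higher and Xaf1 lower. Cdkn1c, an imprinted inhibitor of the cell cycle (chromosome 7, 150644244 to 150646955), had 24.9 FPKM in the knockout and 8.22 in the control at day 0, and 143 against 24.0 at day 4. Otx2, a factor of the formative and primed states (chromosome 14, 49277352 to 49287319), had 29.0 against 4.20 FPKM at day 0 and 8.24 against 3.02 at day 4. Usp26, an X-linked ubiquitin protease gene (chromosome X, 49107136 to 49154410), had 23.3 against 5.77 and 7.96 against 1.80 FPKM. Imprinted Mest (1.17 and 1.51 at days 0 and 4), Fndc3c1 (1.21 and 1.45), Zfp936 (1.14 and 1.07), Klk1b22 (1.38 and 1.07) and Glipr1 (0.98 and 1.59) were also higher at both days. Rps27 (3.06 and 5.41), a ribosomal protein gene with processed copies, and Npcd (2.82 and 2.02), which overlaps Nptxr (-2.96 and -0.93) at the same coordinates, are uncertain. Lower at both days were the interferon-induced Xaf1 (-1.71 and -1.42), the transcription factors Cebpb (-1.76 and -1.23), Junb (-1.48 and -1.11) and Jund (-1.03 and -1.04), and Rnaseh2c, Lgals3bp, Ppp1r3b, Cbln1, Sft2d1 and Mex3d. Xaf1 and Lgals3bp lie on chromosome 11, which was lower as a whole in the knockout than in its control.

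At day 0 the largest differences were those of Snurf (4.49), which shares its transcript with Snrpn, Btg3 (2.89) and Scarna6 (2.59), each at or near 0 in the control and so uncertain, and the fibroblast collagen Col1a2 (19.7 FPKM in the control, 2.29 in the knockout), Crabp1 (-1.98), Cirbp (-1.88) and Rbmxl2 (-1.83). At day 4 the contractile genes Acta2 (96.2 against 10.9 FPKM) and Tagln (288 against 39.7 FPKM) were higher in the knockout, together with Rplp2-ps1 (2.73), a ribosomal pseudogene. Nrn1 (-1.95), the interferon regulator Irf7 (-1.86), H2-T9 (-1.79), Cbln4 (-1.75) and Gas1 (-1.71) were lower. In all 71 genes were higher and 153 lower by at least 1 at day 0 (105 and 116 with quantile scaling), and 142 and 93 at day 4. The same direction at both days was seen for 9 higher genes, with 0.839 expected of independent lists, and 13 lower genes, with 1.18 expected, while 7 genes changed sides. No expected number was computed for the genes that changed sides. The days shared the table's normalisation but no library. The same clones and control cells were used at both days, so a lasting difference between them also raises the overlap. In the authors' deposited table, the genes significantly higher in the knockout at day 0 numbered 6 (Otx2, Smc1b, Tmem53, Usp26, Zscan4a and Zscan4d) and those lower 12, including Col1a2, Grb10, Cirbp and Xaf1. For genes of chromosome 11, such as Xaf1 and Grb10, the shift of the whole chromosome is part of the difference. At day 4 it marks 15 higher, including Acta2, Acta1, Tagln, Myl9, Cdkn1c and Tnc, and 1 lower, Igfbp5.

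The gene lists differed between the days. At day 0 the cleavage-stage-like list had a median difference of 1.29, above all random lists (100th percentile), with Zscan4d at 15.1 against 3.50 FPKM and Zscan4c at 13.9 against 3.41 FPKM, although these are members of a family of similar sequence. Proliferation was at 0.19 (percentile 99.8), while feeder fibroblast (-0.53, percentile 0.18), pluripotency (-0.31, percentile 0.15) and formative and primed pluripotency (-0.42, percentile 0.945) lay low. In the formative list Otx2 went the other way. At day 4 p53 targets were at 0.56 (100th percentile), with 15 of 15 genes above 0, including Perp (1.01), Eda2r (0.92) and Plk2 (0.88). Pluripotency was at 0.46 (100th percentile), with 22 of 24 genes above 0, including Nanog (47.0 against 16.8 FPKM) and Tdgf1 (54.3 against 21.5 FPKM). FGF and ERK response was at 0.52 (100th percentile), although its mean was 0.25, with 10 of 14 genes above 0 and 1 lower by at least 1. Feeder fibroblast was at 0.39 (percentile 99.7, led by Tagln and Acta2) and primitive endoderm at 0.37 (percentile 99.3, Gata6 1.10 and Col4a1 1.05). Without the genes of chromosome 11 the feeder fibroblast and primitive endoderm lists were at 0.59 and 0.60, over 8 genes each. Differentiated trophoblast was at -0.56, below all random lists, with Hand1 at 49.3 against 109 FPKM and Dlx3 at 21.9 against 44.7 FPKM. Both lie on chromosome 11, which was lower as a whole in the knockout than in the SATB1 control. It was also lower in both ALKBH1 arms than in that control, so the shift may lie in the control and not in the knockout. Without the genes of chromosome 11 the list was at -0.40 over 8 genes (percentile 0.03). Hypoxia and glycolysis was at -0.23 (percentile 0.19) and imprinted genes at -0.15 (percentile 0.97, although Cdkn1c and Mest were higher). Trophoblast stem and trophectoderm, epithelial junction, germline, Hox, methylation enzyme, cholesterol synthesis and neuroectoderm lists lay within the middle 95% of random lists at both days, and only 2 primitive streak and mesoderm genes were measured, Wnt3 (0.47 and 0.77) and Snai1 (-0.22 and -0.35). The medians named here as high or low kept their sign under quantile and median scaling.

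**Figure D4:**
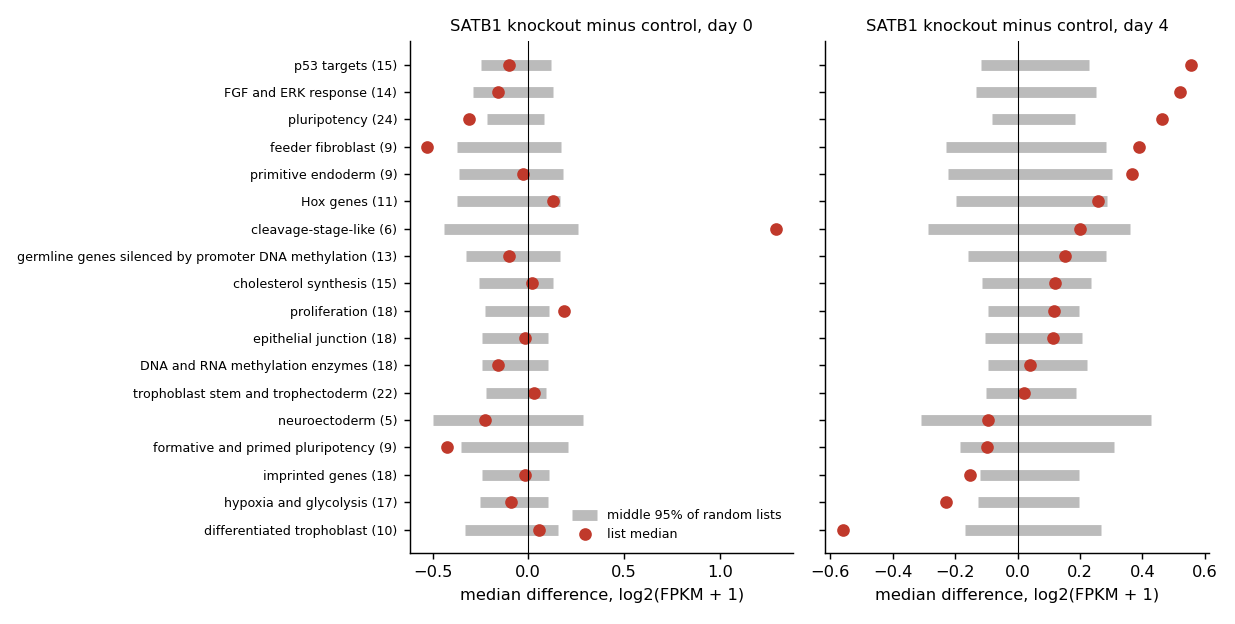
Median difference in log2(FPKM + 1), SATB1 knockout minus control (x axis), of each gene list (y axis, number of measured genes in brackets) at day 0 and day 4. Red points are list medians and grey bars the middle 95% of 10000 random lists matched on mean expression. At day 0 the cleavage-stage-like list is at 1.29, and at day 4 the differentiated trophoblast list is at -0.56 and the p53 list at 0.56.

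From day 0 to day 4, both SATB1 genotypes lost pluripotency expression and gained trophoblast expression. In the control the list medians were -3.13 for pluripotency, 3.12 for trophoblast stem and trophectoderm, 3.04 for differentiated trophoblast and 1.46 for epithelial junction. In the knockout they were -2.32, 2.86, 3.04 and 1.62. The feeder fibroblast list went down by a median of -2.23 in the control and -0.20 in the knockout, and the cleavage-stage-like list by -1.60 and -2.64. Germline genes had medians of -1.60 and -1.32. Genes that differed by at least 1 numbered 1500 higher and 1492 lower at day 4 in the control, and 1665 and 1002 in the knockout (1343 and 1344 with quantile scaling). The difference of these differences, which was not tested, was at least 1 in 360 genes and at most -1 in 138, over a median of all genes of 0.12. The authors' deposited table marks 627 genes in the control, 351 higher and 276 lower, and 1540 in the knockout, 1052 higher and 488 lower. The knockout had 2 libraries per day and the control 1, so these 2 counts do not compare the genotypes on equal terms. By the size rule, 2992 genes differed in the control and 2667 in the knockout.

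The control time courses of both tables agreed across genes. The day 4 minus day 0 difference in the ALKBH1 control correlated with that in the SATB1 control (Spearman 0.77 ± 0.0066, SD over chromosome bootstraps, 11635 genes), and 78.3% of genes had the same sign. These tables share no library, and genes are not independent replicates.

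The ALKBH1 overexpression effect was set against the SATB1 knockout effect, since the series title sets DNA N6-methyladenine against SATB1. Across genes the Spearman correlation was -0.11 ± 0.019 at day 0 and -0.02 ± 0.015 at day 4 (SD over chromosome bootstraps). At day 0, 42 genes were higher by at least 1 in overexpression and lower in the knockout, with 8.74 expected of independent lists, and 19 were lower and higher, with 3.25 expected. In the same direction there were 13 higher in both (4.15 expected) and 4 lower in both (6.85 expected). At day 4, 28 genes were lower in overexpression and higher in the knockout (6.42 expected), 13 were higher and lower (4.90 expected), 13 were higher in both (7.44 expected) and 9 lower in both (4.23 expected). Acta2, Tagln and Myl9 were among those lower in overexpression and higher in the knockout at day 4, and were chosen after their values were seen.

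Each effect was also placed on the day 4 minus day 0 axis of the control of the other table. The SATB1 knockout effect at day 4 had a correlation of -0.17 ± 0.013 and a slope of -0.0731, so genes that increase over the 4 days tended to be lower in the knockout. At day 0 the correlation was -0.004 ± 0.0096. The ALKBH1 overexpression effect had -0.16 ± 0.016 at day 4, with a slope of -0.0758, and -0.12 ± 0.017 at day 0.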

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

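These list results stood out because the effect of overexpression differed between days by a test of the slope difference itself. The slope per day of the cholesterol synthesis list, overexpression minus control, had a median of -0.27 over 14 genes (camera adjusted p = 1.1e-08), and 0 genes passed singly. The slope per day of the hypoxia and glycolysis list had a median of -0.23 over 18 genes (camera adjusted p = 0.000119). Neither passed with an estimated correlation (adjusted p = 0.904). No biological or technical explanation was tested for them.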

How the results depend on the processing

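The alternatives chosen after seeing the data leave out days 0 and 4 together, remove chromosome medians, or leave out the genes of chromosomes 2, 10 and X, of chromosome 11, or of chromosomes 2, 10, 11 and X. The limma fit to the SATB1 table, with its alternatives, was also chosen then. Pseudocounts, filters, scalings, the variance trend and the single-day and single-arm fits were planned. No correlation across genes changed sign under the alternatives run, and the slope difference called 0 genes under each. Among single named genes, 3385 results were the same under an alternative, 427 were no longer past the threshold, 50 newly passed, 26 moved and none called changed sign. Over all called genes, 80 changed sign in the arm effect with chromosome medians removed. In the time course 12 did without day 0, 10 without days 0 and 4, and 1 with the control arm alone. For the clones of the SATB1 table, no paired analysis was possible because the 2 knockout clones share 1 value per day, so neither a clone block nor a fit without a clone was run. The ALKBH1 arms were paired by day. Depth limits the low genes of overexpression day 2, whose relative depth was 0.0934. The cause of the changes below was not tested, apart from fits with fewer libraries or genes.

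Leaving out 1 day at a time, the arm effect had 806 to 1415 genes higher and 568 to 1314 lower, and the time course 2209 to 3240 rising and 1864 to 2839 falling. Without days 0 and 4 the arm effect had 0 higher and 0 lower (limma, 3793 at an unadjusted p below 0.05), with 2 residual degrees of freedom. The coefficients of the 3597 genes had the same sign and a median size of 0.65 against 0.67, but these genes were called on days that include those kept. Without the day block it had 297 and 269. The control arm alone had 1980 rising and 1827 falling, the overexpression arm alone 1010 and 1038, and a mean of at least 5 FPKM left 1780 falling. The SATB1 genotype fit called 0 higher and 0 lower, 2 and 1 with a mean of at least 5 FPKM (Rps27 and Usp26, and Xaf1), and 4 and 1 with limma trend (also Cdkn1c and Npcd). Camera with an estimated correlation called 0 lists for the arm effect, 0 for the time course and 0 for the slope difference. At the preset correlation it called 3, 8 and 2, and 3, 9 and 3 with a pseudocount of 0.1.

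With a pseudocount of 0.1, genes higher at single days in ALKBH1 overexpression were 1421, 1239, 1468, 1007 and 1283 at days 0, 2, 4, 5 and 6, and 841 were lower at day 2. For the SATB1 knockout they were 183 higher and 394 lower at day 0 and 369 and 175 at day 4. With a mean of at least 5 FPKM the ALKBH1 genes higher were 494, 426, 589, 349 and 435, the knockout counts were 34 and 100 at day 0 and 88 and 42 at day 4, and genes lower at day 4 than at day 0 were 894 in the SATB1 control and 635 in the knockout.

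At a 1.5-fold difference in place of 2-fold, ALKBH1 overexpression had 2288 higher and 2020 lower at day 0, 1993 and 1615 at day 2, 2137 and 1990 at day 4, 1705 and 2301 at day 5, and 2123 and 2188 at day 6. The knockout had 361 and 1002 at day 0 and 667 and 479 at day 4. From day 0 to day 4 the SATB1 control had 2807 and 3014, and the knockout 3316 and 2292.

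Of the correlations across genes, overexpression against knockout was -0.0773 at day 0 and -0.0035 at day 4 with a mean of at least 5 FPKM, and -0.14 at day 0 without chromosomes 2, 10, 11 and X. On the differentiation axis, the knockout at day 4 was -0.18 with a pseudocount of 0.1 and -0.14 with quantile scaling, and the knockout at day 0 was -0.019 with a mean of at least 5 FPKM. Overexpression at day 4 was -0.13 with that filter, -0.13 with quantile scaling and -0.19 without these chromosomes, and at day 0 it was -0.0793 with that filter and -0.16 with quantile scaling. The control time courses correlated at 0.76 with quantile scaling. The other counts and correlations stayed within 1.5 times or within the spread.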

Other observations

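Acta1 and Myl9, chosen after their values were seen, were lower in ALKBH1 overexpression and, at day 4, higher in the SATB1 knockout. Acta1 had 8.02 to 43.2 FPKM in the ALKBH1 control at days 0 to 4 and 0.486 to 4.91 in overexpression, and in the SATB1 table, 98.7 FPKM in the knockout against 22.0 in the control at day 4 and 21.9 against 24.9 at day 0. Myl9 had 33.7 FPKM in the ALKBH1 control at day 4 and 6.62 in overexpression, and in the SATB1 table, 56.7 FPKM in the knockout against 12.0 at day 4 and 13.6 against 7.53 at day 0. For Tagln the SATB1 values at day 0 were 319 FPKM in the knockout and 280 in the control, a difference of 0.19.

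The Y-linked Ddx3y had 5.04 to 9.03 FPKM in the ALKBH1 control and 16.4 to 24.5 FPKM in overexpression, against 16.2 to 26.6 FPKM over the SATB1 conditions. Eif2s3y had 27.2 to 43.5 FPKM in the ALKBH1 control and 22.8 to 42.2 in overexpression. On chromosome X, 47.5% of 474 tested genes were higher and 1.05% lower in overexpression, while on chromosome 2 3.98% of 980 were higher and 30.9% lower. Against the SATB1 control, chromosome 11 lay at -0.38 and -0.47 in the ALKBH1 control at days 0 and 4, at -0.42 and -0.52 in overexpression, and at -0.32 and -0.29 in the SATB1 knockout. In the same order, chromosome 2 lay at 0.06 and 0.01, at -0.30 and -0.37, and at 0.0042 and 0.0045, chromosome 10 at 0.05 and 0.002, at -0.24 and -0.36, and at -0.03 and -0.04, and chromosome X at -0.22 and -0.18, at 0.32 and 0.17, and at 0.10 and 0.0045. Chromosome 11 was thus lower than in the SATB1 control in each of the other groups, so its shift may lie in that control and not in the knockout. The ALKBH1 and SATB1 tables were normalised separately.

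For the patterns that follow, the tests were chosen after the result was seen, except the test of GC content and length and the test of equal parts of the chromosomes.

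For the genes that differed between the ALKBH1 arms, the real arrangement gave 3597 genes. The 16 splits that swap libraries within days are too few for a share under 0.05 (smallest 0.0625), with 1 split as large, the real one, and 1 gene as the highest of the others. Direct dosage of the genes on chromosomes 2, 10 and X is not the whole cause, as a separate fit without these chromosomes still called 2713 genes. That fit tested 10657 genes, 83.9% of all, and called 25.5% of them. An effect of these chromosomes on genes elsewhere was not tested and stays open. In the fit over all chromosomes, 30.9% of the tested genes of chromosome 2 and 31.2% of those of chromosome 10 were lower. On chromosome X 47.5% were higher. The highest shares of any other chromosome were 18.8% lower (chromosome 17) and 21.9% higher (chromosome 1), so a part of the calls may come from these shifts. With chromosome medians removed 1598 genes were higher and 1373 lower, of which 1365 and 1133 were among those called before. Of the 3597 genes, 80 changed sign. For Tagln, feeder fibroblasts in the control libraries are argued against as the only source. The highest fibroblast collagen or matrix gene, Col1a1, reached 3.72% of the Tagln level over days 0, 2 and 4. This rests on feeder cells having collagen at the level of Tagln, which was not measured here. Acta2 and Vim were not compared in this way, so feeder cells stay open as their source. The feeder fibroblast list as a whole was lower in overexpression at these days (-1.36, -2.37 and -0.84), so some excess of feeder RNA in the control stays open. The 2105 genes called without day 6 had a median difference of 0.68 ± 0.018 (SD over chromosome bootstraps) at day 6 in the direction of the call, and 95.5% had that direction. Alkbh1 mRNA differed by 1.31 at day 0 and -0.10 at day 6, so these genes did not follow it at day 6. The fit favours differences that are constant over days, while the Alkbh1 difference had fallen to 0.13 by day 5. Genes that follow the Alkbh1 mRNA of the same day were thus less likely to be called. For genes outside the call such a response stays open. The germline list was at 0.99 at day 0 and 1.28 at day 6, and the FGF and ERK list at -1.08 and -0.98. The slope of the day 6 differences on the day 0 differences over all genes, 0.188 ± 0.028, does not decide, as noise in single libraries lowers it. A lasting effect of the earlier overexpression and a fixed difference between the cultures both stay open, since no second culture of either arm exists in the table.

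Whole chromosomes were shifted between the ALKBH1 arms. GC content and transcript length do not account for it, as the smallest shift of chromosomes 2, 10 and X stayed at 0.34 after both were removed. Copy number of whole chromosomes may contribute, as a hypothesis, since each of 4 equal parts of these chromosomes, by position, was shifted in the direction of its chromosome, with 0.19 as the smallest. A change from 2 to 3 copies would give 0.58. That is not the measure for a loss on chromosomes 2 and 10, which were lower in overexpression. Nor is it for X if the cells had 1 copy, as Y-linked genes were expressed in both arms. Single parts of other chromosomes reached 0.346. DNA was not measured here, so chromosome-wide regulation, as of the X chromosome, stays open.

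Germline genes were higher in the overexpression arm. Direct dosage of X-linked members is not the cause, as the 14 of 15 list members on autosomes had a median of 1.31. An effect of X dosage through other genes was not tested and stays open. Against the SATB1 control, the ALKBH1 control differed by 0.39 at day 0 and by -0.34 at day 4 (list medians, SATB1 control minus ALKBH1 control), and the overexpression arm by -0.67 and -2.15 (SATB1 control minus overexpression). The overexpression arm thus lay further from the outside control at both days, but the ALKBH1 control did not lie within the bound set of 0.3 either, so whether overexpression alone departs from the level of an outside control cannot be told apart from a difference of the tables, which were normalised separately. ALKBH1 overexpression, a culture difference or an earlier loss of DNA methylation at these promoters may each be involved. Alkbh1 mRNA was measured, but no test here parts these, and DNA methylation was not measured in these libraries.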
